A study of Mus musculus with 8 samples.

How the data were processed

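Single-cell RNA sequencing libraries had been prepared from mammary tumors and from lungs of female BALB/cJ mice that carried 4T1 tumors, a mouse mammary carcinoma line that spreads to the lungs. The 8 libraries fall into 4 groups of 2 by tissue (primary tumor or lung) and by the introduced ENPP1 (wild type, WT, or the mutant T238A). Per the labels, the cells had been frozen and thawed before loading on a 10x Genomics 3′ droplet kit. Groups and replicate numbers come from the sample titles.

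The values are counts of unique molecular identifiers (UMIs) per gene and barcode, deposited without normalization. Per the file headers, the matrices were written by Cell Ranger 7.1.0. The submitters' processing notes name Cell Ranger 3.1.0 and the genome build GRCm38, and the difference between the versions is not resolved here. Of the 32285 features, 32235 had a position in the GENCODE annotation of GRCm38 used here. The lowest count per barcode lay between 500 and 507 UMIs in the 8 libraries, so barcodes with fewer UMIs are not part of these matrices. Whether reads in introns were counted is not given in the sources used here. A 3′ count does not separate genes that share their 3′ end.

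Barcodes with at least 200 genes and at most 15% mitochondrial counts were kept, which removed 1407 of 38637 barcodes. Doublets were scored with scrublet as included in scanpy 1.11.5, and the 214 cells above its own threshold (0.575%) were removed. In 5 of the 8 libraries it called under 0.2% of cells, so the caller found few doublets and others will remain. The 37016 kept cells were clustered together on 2500 variable genes, 40 principal components and 15 neighbors with the Leiden method at resolution 1.0 (leidenalg 0.10.2, Python 3.11.15), without correction between libraries. This gave 37 clusters, and clusters of cancer cells were divided again at resolution 0.8. Clusters were named from marker lists fixed before the data were examined, with at least 3 markers detected. Left unnamed were clusters led by markers of another class, mixed by their doublet scores, or led by the thymic genes Rag1, Arpp21 and Dntt or the progenitor genes Mpo, Elane and Prtn3. The thymic and progenitor genes were chosen after the clusters were seen. The unnamed clusters held 1677 cells (4.53%). Class names below stand for cells that resemble the named type by these markers.

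Macrophage cluster 0 was led by Aif1, Ccl8 and C1qb, cluster 2 by Mmp12, Cxcl3 and Arg1, and cluster 3 by Ccl8, C1qa and Ms4a7. Cluster 11 was led by Plcb1, Ccr2 and Clec4a1 and cluster 31 by Cd300e, Ace and Treml4. T-cell cluster 5 was led by Nkg7 and Cd8b1, cluster 10 by Ctla4, Icos and Foxp3, and cluster 25 by Lef1 and Dapl1. B-cell cluster 17 was led by Ighd and Fcer2a, cluster 28 by Igkc and Mzb1, and cluster 29 by Cecr2, Vpreb3 and Ebf1.

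Counts were summed per library and class wherever a class had at least 30 cells in the library, and the sums were tested with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) with TMM scaling, its own filter on low counts and Benjamini-Hochberg adjustment at 0.05. Within a class, all groups with a library kept shared 1 fit. For B cells this held 1 T238A tumor library and no WT tumor library. For cancer epithelial cells it held 1 WT lung library and no T238A lung library. The contrasts were T238A against WT in primary tumors, the same in lungs, the difference between these effects (the interaction), and lungs against primary tumors. A contrast was tested where both of its groups kept 2 libraries. The 6 classes with the most cells were tested: neutrophils, monocytes/macrophages and T cells in every contrast, cancer epithelial cells in primary tumors, and B cells and dendritic cells in lungs. Fold changes are given as log2 with the standard error (SE).

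A total of 31 gene lists, fixed before the data were examined, were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, and again with the correlation estimated from the data. At the preset value 31 of 109 tests passed in primary tumors, 73 of 134 in lungs, 32 of 81 for the interaction and 49 of 81 between tissues. With an estimated correlation 0 lists passed by camera in any of the 4 contrasts, and this holds for every list call below.

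Shares of cells were compared with a 2-sided exact permutation test. With 2 libraries against 2 its smallest p is 0.333, so it cannot pass 0.05. edgeR on the numbers of cells was run as an alternative. Intervals of shares are 95% intervals that cover counting error only, as do floors of 3 counts.

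The genes to be named followed a rule fixed before the data were examined: genes chosen from the study's subject, then per tissue the 5 largest rises and falls in the 3 classes with the most calls among genes with a mean log2 CPM of at least 5, then up to 4 members with the smallest p of each list that passed. The text gives a selection of these. Nr1h4 in lung neutrophils and Acvr2a, Fgf13, Pard3, Malt1 and Ntrk3 in T cells fall outside the rule and were chosen after their values were seen. Fam129c and Reln met the rule in B cells but lead cluster 29, so their changes over all B cells are not given as results.

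The tests were tried on simulated counts with 200 changed genes. Among 4-fold changes the share recovered was 82% in monocytes/macrophages and 67% in neutrophils of primary tumors, and 76% in monocytes/macrophages of lungs. Among 2-fold changes in T cells of primary tumors it was 24%. Unchanged genes were called too, from 4 (interaction in neutrophils) to 33 (dendritic cells of lungs). The 33 stood beside 27 recovered 2-fold and 73 recovered 4-fold changes. In tumor neutrophils 18 stood beside 41 and 67, and in lung monocytes/macrophages 19 beside 47 and 76. In these trials false calls were thus a larger share of the calls than the 0.05 set. Of 15 simulated lists of 30 genes raised 1.5-fold camera called 15 at an unadjusted p under 0.05. Of 15 flat lists it called 0. The simulated genes were drawn independently, so this trial does not cover lists whose genes vary together.

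Alternatives were the scaling of DESeq2, no filter on low counts, DESeq2 1.42.0 as the test, each tissue fitted alone, blocks by replicate number, stricter cell filters (500 genes, 10% mitochondrial), doublets kept, Leiden resolution 0.5, shares among immune cells, and each library left out in turn. Chosen after seeing the data were the removal of the top 5% of doublet scores, thymocyte-led clusters counted as T cells or left out, lung monocyte clusters only, B cells without cluster 29, and macrophage clusters 0, 2 and 3 one at a time.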

Results

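The study asked how ENPP1 on cancer cells acts on tumors and their immune cells. ENPP1 is a membrane-bound and secreted hydrolase that degrades extracellular cGAMP, the messenger made by cGAS that activates STING, and also ATP. 4T1 cells without their own Enpp1 had been made to overexpress wild-type ENPP1 or the catalytically inactive mutant T238A. Primary tumors at 1000 mm3 and lungs holding metastases came from 2 mice per condition.

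The primary tumor libraries held 27358321 and 26744998 UMIs for WT and 40291707 and 21013014 for T238A, in 3190, 1715, 4076 and 1288 kept cells. The lung libraries held 46489957 and 17441058 UMIs for WT and 41264395 and 24458540 for T238A, in 9954, 3755, 8631 and 4407 kept cells. The median count per kept cell was 3259.5 and 8255 UMIs in the WT tumors, 3892.5 and 6039 in the T238A tumors, and 3046 to 3888 in the lungs. The first T238A tumor lost 13.1% of its barcodes to the filters, against 4.46% to 6.17% in the other tumors and 0.838% to 2.81% in the lungs.

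Enpp1 was examined first, since the cell lines lack the endogenous gene. Enpp1 (ENSMUSG00000037370) lies on chromosome 10 from 24637914 to 24712159, minus strand, in GRCm38. In cancer epithelial cells of primary tumors it was counted at 1.39 ± 0.213 CPM in WT and 2.64 ± 1.46 CPM in T238A (SD, n = 2), from 10 and 18 UMIs and from 65 and 16 UMIs. The fold change was 0.84 ± 0.55 (log2 ± SE; edgeR adjusted p = 0.449). Tumor monocytes/macrophages held more, 27.0 ± 2.77 CPM in WT and 33.3 ± 5.92 CPM in T238A (SD, n = 2). Cancer cells of the first WT lung had 0 of 2220602 UMIs, which allows up to 1.35 CPM, and the 19 cancer cells of the second WT lung had 31 UMIs. Whether the introduced cDNA carries the 3′ end counted here is not known, so these counts neither verify nor contradict the labels.

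To see whether the make-up of the tumors differed between the constructs, shares of cells were compared per library. T238A tumors held 9.10% ± 0.458 T cells against 5.04% ± 2.18 in WT tumors (SD, n = 2), and 1.31% ± 0.0931 B cells against 0.224% ± 0.0953. Fibroblasts made up 4.25% ± 2.60 against 1.49% ± 0.0302. For each of these classes both T238A tumors lay above both WT tumors, with an exact permutation p of 0.333, the smallest the design allows. Innate lymphoid type 2 cells numbered 20 and 1 in the T238A tumors and 0 of 3190 and 0 of 1715 in the WT tumors, which allows shares of up to 0.094% and 0.175%. The groups overlapped for neutrophils (27.7% ± 12.1 in WT, 22% ± 8.68 in T238A), monocytes/macrophages (44.2% ± 4.05, 38.3% ± 6.07) and cancer cells (18.7% ± 10.8, 21.1% ± 1.63), with an exact permutation p of 0.667, 0.667 and 1. By edgeR on numbers of cells, the B-cell share was higher in T238A tumors (log2 ratio 2.62, adjusted p = 0.00839), from 5 and 5 cells in WT and 56 and 16 in T238A, while T cells (0.84, adjusted p = 0.528) and fibroblasts (1.53, adjusted p = 0.0867) did not pass. The libraries differed in depth per cell and in the share of barcodes filtered, either of which can set shares.

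In lungs the cancer cells and B cells stood out. Cancer epithelial cells numbered 97 and 19 in the WT lungs and 4 and 0 in the T238A lungs, shares of 0.740% ± 0.331 and 0.0232% ± 0.0328 (SD, n = 2). The 0 of 4407 cells allows up to 0.0681%. B cells made up 11.1% ± 1.49 of T238A lungs and 3.88% ± 0.859 of WT lungs. Dendritic cells stood at 1.06% ± 0.145 against 2.54% ± 1.64 and alveolar macrophages at 2.37% ± 0.0108 against 1.81% ± 0.185. For each of these the groups did not overlap, with an exact permutation p of 0.333. Under edgeR on numbers of cells the cancer share was lower (log2 ratio -4.57, adjusted p = 4.8e-05) and the B-cell share did not pass (1.51, adjusted p = 0.0945). Dendritic cells (-1.27, adjusted p = 0.135) and alveolar macrophages (0.385, adjusted p = 0.731) did not pass either. Neutrophils made up 60.2% ± 21.9 of WT lungs and 59.9% ± 0.0672 of T238A lungs. Of the cells in the first WT lung, 9.39% belonged to an unnamed cluster led by the thymic genes Arpp21 and Rag1, against 0.0908% to 0.348% in the other lungs.

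**Figure D1:**
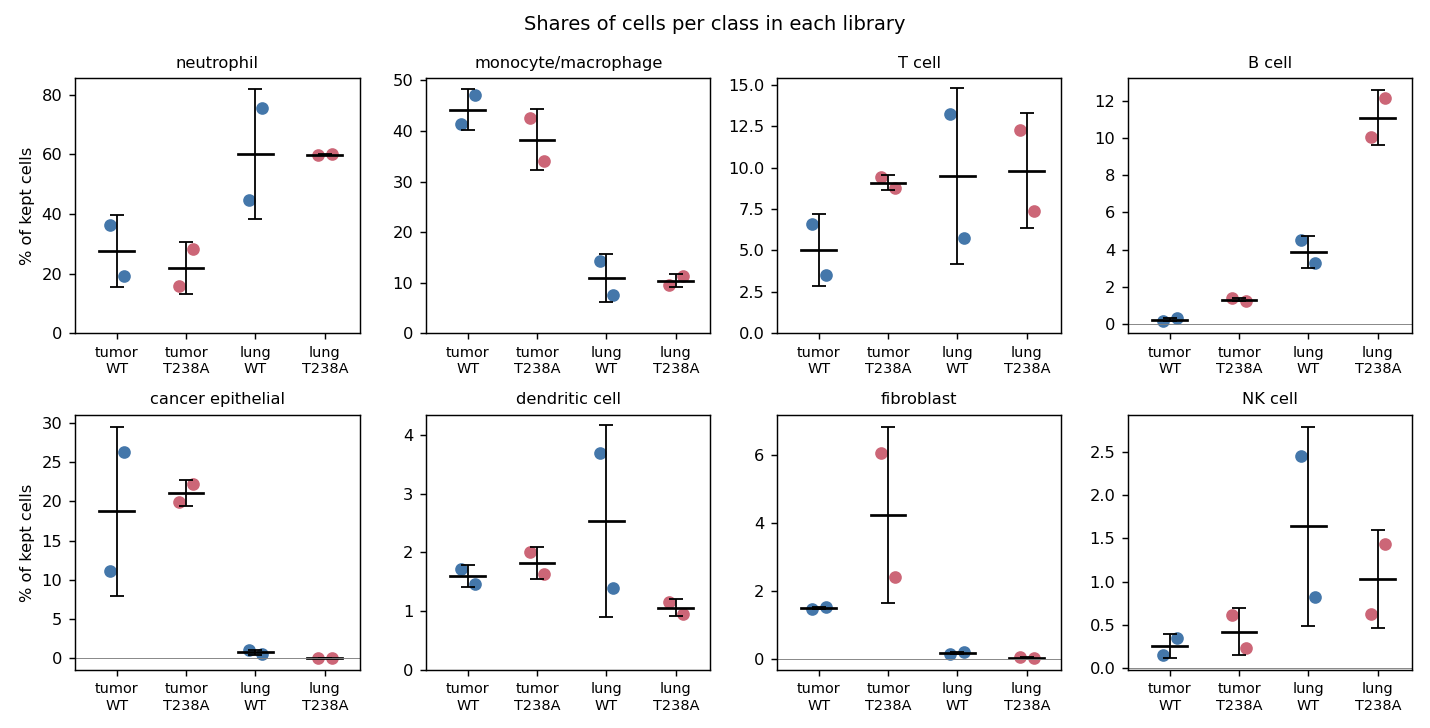
Share of kept cells (percent) per library for the main cell classes in primary tumors and lungs, by construct, with points for single libraries and bars for the mean of 2 and the SD. B cells reach 11.1% on average in T238A lungs against 3.88% in WT lungs.

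Expression was then compared between T238A and WT tumors, class by class, to find which programs in the tumor differ with ENPP1 activity. Monocytes/macrophages of T238A tumors had higher levels of interferon-stimulated and MHC class II genes. Oxidative phosphorylation genes were lower, less so against genes of similar span and expression. The interferon regulator Irf7 rose by 1.38 ± 0.18 (log2 ± SE, edgeR adjusted p = 0.0085), the double-stranded RNA sensor Oas2 by 1.51 ± 0.21 (0.011) and Slfn5 by 1.32 ± 0.21 (0.017). The MHC class II chains H2-Eb1, H2-Ab1 and H2-Aa rose by 1.66 ± 0.24, 1.56 ± 0.23 and 1.61 ± 0.24, and the peptide-loading gene H2-DMb1 by 1.48 ± 0.14 (adjusted p = 0.0030). In all, edgeR called 333 of 12896 genes, 192 higher and 141 lower.

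Of 49 tested members of the type I interferon list in these cells, 15 rose and 0 fell, and 27 rose when adjusted over the list alone. The median was 0.62 (camera adjusted p = 1.6e-22), with adjusted p = 0.567 with an estimated correlation. Of 12 MHC class II members 6 rose (9 adjusted over the list alone), with a median of 1.32 and adjusted p = 6.9e-15, and adjusted p = 0.567 with an estimated correlation. Of 56 oxidative phosphorylation genes 9 fell (28 adjusted over the list alone), among them the respiratory chain subunits Ndufb2 (-0.88 ± 0.14) and Cox5b (-0.73 ± 0.13). The median was -0.39, adjusted p = 9.4e-15, and adjusted p = 0.241 with an estimated correlation, and -0.156 after matching on span and expression. Of 32 hypoxia and glycolysis genes 1 fell, Ankrd37 (-1.41 ± 0.29), and 14 adjusted over the list alone, with 1 higher (median -0.46, adjusted p = 9.6e-07, and adjusted p = 0.593 with an estimated correlation). The chemokine list had a negative median (-0.53) and a positive mean (0.07), and camera gave it as lower (adjusted p = 0.0188, and adjusted p = 0.589 with an estimated correlation). Without the first T238A tumor its adjusted p was 0.209, without the first WT lung 0.357 and without the second 0.465. The cGAMP-STING list did not pass in any of the 4 classes of tumor cells (adjusted p = 0.0963 to 0.755), nor did the ATP-adenosine list (0.0888 to 0.833).

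Among genes with a mean log2 CPM of at least 5 and groups that did not overlap, the largest rises in these macrophages were of Adamdec1, a secreted protease of tissue macrophages (4.09 ± 0.43), the terminal complement component C6 (3.16 ± 0.40), the growth factor Nrg1 (2.98 ± 0.38), the acid phosphatase Acp5 (2.85 ± 0.40) and the matrix protein Spon1 (2.67 ± 0.16, adjusted p = 0.00011). The largest falls by the same rule were of F13a1, a clotting factor subunit made by monocytes (-1.77 ± 0.28), the chemokines Cxcl14 (-1.55 ± 0.17) and Ccl6 (-1.33 ± 0.20), and the GTPase Rhoc (-1.46 ± 0.21). The B-cell attractant Cxcl13 had 4 and 0 UMIs in WT and 173 and 38 in T238A. Arg1 (-0.62 ± 0.51), Nos2 (-0.00 ± 0.72), Cxcl9 (0.09 ± 0.56) and Tmem173, which encodes STING (0.38 ± 0.12, adjusted p = 0.13), did not pass. Cluster 0 held 23.6% and 12.1% of these cells in WT and 40.5% and 36.3% in T238A. Cluster 2 held 36.3% and 47.6% against 16.4% and 24.9%, and cluster 3 held 36.3% and 34.8% against 38.9% and 35.2%. The median count per cell was 920 UMIs in cluster 0, 6542 in cluster 2 and 13487 in cluster 3. The larger share of cluster 0 in T238A is thus one of cells with low counts. Within clusters 0, 2 and 3 the interferon list had medians of 0.55, 0.55 and 0.72 and the MHC class II list of 1.22, 0.64 and 1.24. The count of 333 became 58 and 27 without the first and second WT tumor, 187 without the second T238A tumor, and 118 and 115 without the first and second T238A lung. Of the 26 named genes past the threshold, 3 (Cxcl14, H2-DMb1, Spon1) stayed past it whichever library was left out.

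Neutrophils of T238A tumors had lower levels of glycolysis genes. The glycolytic enzymes Tpi1 and Pfkl fell (-0.91 ± 0.18 and -0.77 ± 0.16, log2 ± SE), as did the cytokine Mif (-1.08 ± 0.17). Of 30 hypoxia and glycolysis genes 4 fell (13 adjusted over the list alone), with a median of -0.48 and adjusted p = 7.2e-16, and adjusted p = 0.567 with an estimated correlation. Of 56 oxidative phosphorylation genes 1 fell, Cox8a (-0.94 ± 0.17), and 17 adjusted over the list alone, with 1 higher (median -0.37, and -0.0432 after matching on span and expression; adjusted p = 2.2e-07, and adjusted p = 0.628 with an estimated correlation). Of 34 genes of suppressive neutrophils 0 passed edgeR over all genes and 14 were lower adjusted over the list alone (adjusted p = 6.8e-07, and adjusted p = 0.589 with an estimated correlation). Dissociation and heat-shock genes were lower as a list in the same cells, with 3 of 28 lower adjusted over the list alone (adjusted p = 0.00329, and adjusted p = 0.567 with an estimated correlation), as was the complement and lysosome list of macrophages, with 1 of 23 called and 5 lower and 2 higher adjusted over the list alone (adjusted p = 0.0369, and adjusted p = 0.853 with an estimated correlation). Without the second T238A tumor these lists had adjusted p = 0.0976 and 0.510, and without the first WT tumor the complement and lysosome list had 0.321. Tcf7l2, a transcription factor of Wnt signaling, rose by 1.42 ± 0.24 and the phosphodiesterase Pde4d by 1.35 ± 0.24, while the mitochondrial import gene Timm8b (-1.37 ± 0.20) and the interferon-induced exonuclease Isg20 (-1.15 ± 0.22) fell. Il1b (-0.28 ± 0.21), Cxcl2 (-0.97 ± 0.24, adjusted p = 0.071), Arg2 (0.06 ± 0.17) and Cd274 (0.07 ± 0.17) did not pass. edgeR called 79 of 10907 genes, 30 higher and 49 lower (38.0% higher), and with the size factors of DESeq2 134, 36 higher and 98 lower (26.9% higher). The count was 1 and 46 without the first and second WT tumor, 7 without the first T238A tumor, and 38 and 37 without the first and second T238A lung, and 0 of the 17 named genes past the threshold stayed past it in every such fit.

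Cancer epithelial cells of T238A tumors had higher levels of the keratins Krt14 and Krt7 and of a few interferon gamma-induced genes. The listed keratins Krt8, Krt18 and Krt19 were not among the markers called. The basal keratin Krt14 rose by 3.60 ± 0.46, Krt7 by 2.23 ± 0.18 and the tight-junction gene Cldn4 by 3.19 ± 0.39 (log2 ± SE; edgeR adjusted p = 0.040, 0.015 and 0.037). Matrix protease Mmp9 (5.66 ± 0.66), the kinase gene Tnik (3.93 ± 0.23) and the metalloprotease Adam12 (2.71 ± 0.26) rose. The G-protein subunit Gng11 (-2.10 ± 0.20) and the adhesion gene Nectin3 (-1.71 ± 0.20) fell. Of 9 epithelial markers 3 rose (4 adjusted over the list alone; adjusted p = 1.5e-08, and adjusted p = 0.589 with an estimated correlation). Of 34 interferon gamma-induced genes 2 rose, the tryptophan-degrading enzyme Ido1 (2.84 ± 0.44) and the protease inhibitor Serpina3g (3.40 ± 0.44), and 4 adjusted over the list alone (adjusted p = 4.2e-06, and adjusted p = 0.761 with an estimated correlation). In the type I interferon list 0 of 48 genes passed edgeR over all genes and 6 were higher adjusted over the list alone (median 0.46, adjusted p = 6.2e-05, and adjusted p = 0.731 with an estimated correlation). Oxidative phosphorylation genes had a median of -0.39 (-0.148 after matching on span and expression) with 2 of 56 lower (5 adjusted over the list alone; adjusted p = 2.8e-08, and adjusted p = 0.601 with an estimated correlation). The groups differed in the mix of sub-clusters: one led by Wfdc2, Hmga2 and Hhip held 85 and 130 cells in WT and 14 and 1 in T238A. Another led by the same genes held 19 and 116 against 31 and 10, where the groups overlapped. One led by Hmga2 and Samd12 held 0 and 3 against 149 and 41. edgeR called 267 of 13995 genes, 189 higher and 78 lower, with 14 and 0 without the first and second T238A tumor, and 0 of the 17 named genes past the threshold stayed past it in every fit with a library left out.

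In T cells of tumors edgeR called 5 of 9564 genes, each higher in T238A. These were the activin receptor Acvr2a (2.31 ± 0.31), Fgf13 (1.58 ± 0.19), the polarity gene Pard3 (1.76 ± 0.27) and the receptor gene Ntrk3 (1.87 ± 0.31). Malt1, a signaling protein of the antigen receptor, was the last (1.09 ± 0.17). Fgf13, Pard3 and Ntrk3 are long genes. Fold changes in these cells went with genomic span, and the called genes were not matched on it. Of 56 oxidative phosphorylation genes 0 passed edgeR over all genes (1213 of all tested genes had an unadjusted p under 0.05, and DESeq2 called 76 of the 479 genes it gave an adjusted p) and 28 were lower adjusted over the list alone. The median was -0.53 (-0.321 after matching on span and expression), adjusted p = 1.4e-20, and adjusted p = 0.567 with an estimated correlation. Genes of naive and memory T cells had a median of 0.49 with 3 of 16 higher adjusted over the list alone (adjusted p = 0.0041, and adjusted p = 0.703 with an estimated correlation), among them the transcription factor Lef1 (0.96 ± 0.22). Without the first WT tumor the adjusted p of that list was 0.322. Values for Cd8a (-0.39 ± 0.23), Gzmb (-0.84 ± 0.37), Ifng (0.19 ± 0.35), Pdcd1 (-0.81 ± 0.27) and Foxp3 (0.03 ± 0.39) did not pass. The count of 5 was 0 without the first WT tumor, 39 without the second T238A tumor, and 2 and 2 without the first and second T238A lung, and 0 of the 5 genes stayed past the threshold in every such fit.

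Fold changes also went with genomic span in tumors, as in lungs. Across genes, which are not independent replicates, Spearman's rho between fold change and span was 0.240 in neutrophils, 0.232 in monocytes/macrophages, 0.306 in T cells and 0.213 in cancer cells of tumors, and 0.356 in T cells, 0.196 in B cells, 0.166 in neutrophils, 0.154 in dendritic cells and 0.0717 in monocytes/macrophages of lungs. With genes put in 5 groups of equal size by span, the median in tumor neutrophils was -0.22 in the shortest group and 0.25 in the longest. Oxidative phosphorylation genes are short, with a median span of 6844 bases. Single called genes were not matched on span, so length is not separated from their changes. Some named genes that rose are long, such as Pde4d in tumor neutrophils and Tnik in cancer cells. Some that fell are short, such as Timm8b in tumor neutrophils. Others went the other way, such as Irf7 (short, higher) and F13a1 (long, lower) in tumor monocytes/macrophages.

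**Figure D2:**
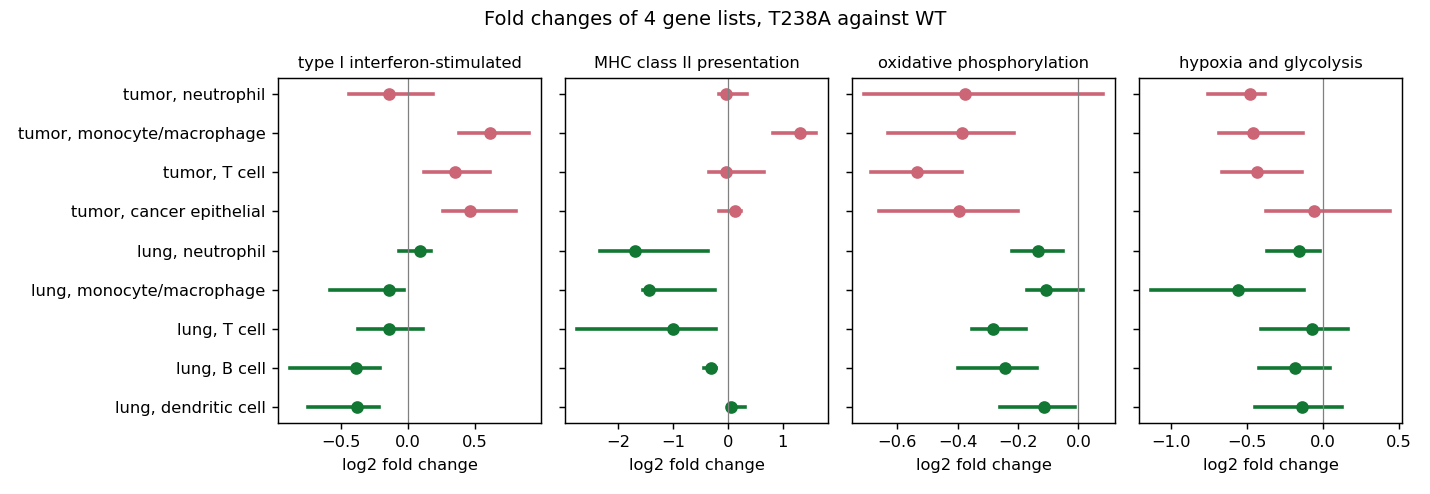
Median log2 fold change, T238A against WT, with quartiles over the members of 4 gene lists (type I interferon-stimulated, MHC class II, oxidative phosphorylation, hypoxia and glycolysis) in each tested class of tumor cells and lung cells. The MHC class II median is 1.32 in tumor monocytes/macrophages and -1.43 in those of lungs.

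The same comparison in lungs asked which programs differ where metastases grow. Lung monocytes/macrophages of T238A mice had lower levels of cell cycle, MHC class II and alternatively activated macrophage genes. The secreted phosphoprotein Spp1 fell, at -4.49 ± 0.30 (log2 ± SE; edgeR adjusted p = 0.00015), as did the complement chains C1qb (-3.45 ± 0.51) and C1qc (-3.29 ± 0.37), arginase Arg1 (-3.89 ± 0.59), the chemokine Cxcl14 (-5.13 ± 0.27) and the angiogenic factor Vegfa (-2.41 ± 0.28). The mitotic genes Cdk1 (-3.34 ± 0.35), Top2a (-2.57 ± 0.26) and Kif11 (-2.50 ± 0.26) fell too. Nt5e, the ectoenzyme that makes adenosine from AMP, had 203 and 62 UMIs in WT and 1 and 3 in T238A. Genes that rose did so by less, such as the peroxisomal transporter Abcd2 (1.02 ± 0.18). edgeR called 258 genes, 21 higher and 237 lower.

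Of 45 cell cycle genes in these cells 19 fell (26 adjusted over the list alone; adjusted p = 3.0e-33, and adjusted p = 0.302 with an estimated correlation). Of 12 MHC class II genes 5 fell (8 adjusted over the list alone), with H2-DMb1 at -1.53 ± 0.15, H2-Eb1 at -1.93 ± 0.24 and Cd74, the invariant chain, at -1.51 ± 0.23 (median -1.43, adjusted p = 1.4e-11, and adjusted p = 0.334 with an estimated correlation). Of 25 genes of alternatively activated macrophages 6 fell (7 adjusted over the list alone; adjusted p = 5.2e-11, and adjusted p = 0.302 with an estimated correlation). Of 32 hypoxia and glycolysis genes 6 fell, and 14 adjusted over the list alone (adjusted p = 1.3e-10, and adjusted p = 0.334 with an estimated correlation). ATP and adenosine genes had 1 of 18 lower (3 adjusted over the list alone; adjusted p = 0.00352, and adjusted p = 0.315 with an estimated correlation), and the cGAMP-STING list did not pass in any class of lung cells (adjusted p = 0.264 to 0.931). Macrophage markers as a list were also lower, with 3 of 8 called (4 adjusted over the list alone; adjusted p = 1.3e-07, and adjusted p = 0.334 with an estimated correlation). The monocyte cluster 11 held 55.3% and 73.9% of these cells in WT lungs and 87.1% and 86.1% in T238A lungs. With clusters 11 and 31 only, an alternative chosen after seeing the data and fitted on the lung libraries alone, edgeR called 1 gene. Such a fit with all clusters called 277. H2-Eb1 then stood at -0.79, Cd74 at -0.52 and, with the sign turned, Top2a at 0.51 and Mif at 0.022 (none called). The calls in lungs thus rest largely on cells of the other clusters. In lung neutrophils 0 of 9 MHC class II genes passed edgeR, over all genes or adjusted over the list alone, with a median of -1.69 (camera adjusted p = 0.00127, and adjusted p = 0.46 with an estimated correlation) and an adjusted p of 0.931 without the first WT lung. Transcripts of other cells were lower in these neutrophils too, with 0 of 8 macrophage markers called (3 adjusted over the list alone; adjusted p = 7.4e-06, and adjusted p = 0.334 with an estimated correlation) and fibroblast markers at a median of -1.76 (adjusted p = 0.000307, and adjusted p = 0.364 with an estimated correlation). The count of 258 was 61 and 137 without the second and first T238A lung, and 88 without the first WT lung, and 11 of the 23 named genes past the threshold, Spp1, C1qc, Cdk1 and Top2a among them, stayed past it in every such fit.

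**Figure D3:**
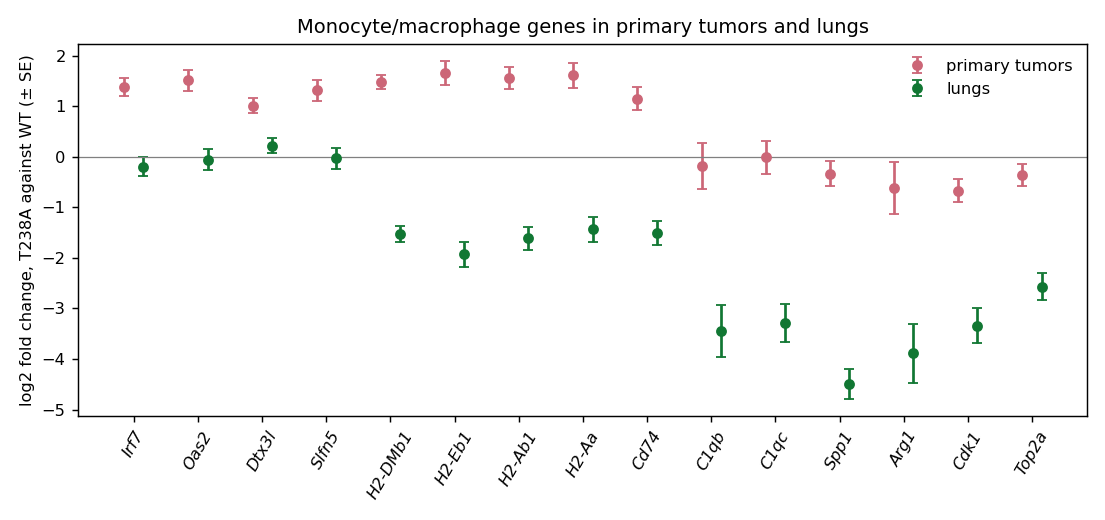
Log2 fold change, T238A against WT, with SE, of 15 genes in monocytes/macrophages of primary tumors and of lungs. H2-Eb1 stands at 1.66 in tumors and -1.93 in lungs, and Spp1 at -4.49 in lungs.

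Taken as a class, lung B cells of T238A mice had higher levels of the scaffold genes Akap12 (2.61 ± 0.23) and Pdzd2 (2.86 ± 0.26) and of the transcription factor Sox4 (2.57 ± 0.45). Levels of the cytokine-signaling inhibitor Socs3 (-2.60 ± 0.26) and of Il1b (-1.88 ± 0.24) were lower. Cluster 29, led by Vpreb3, held 30.5% and 44.2% of the B cells in T238A lungs and 3.13% and 10.6% in WT lungs. Without it, Akap12 stood at -0.10 and Sox4 at -0.23, neither called. The rises of Akap12 and Sox4 thus go with the larger share of cluster 29 and were not seen in the other B cells. Transcripts of other cells were lower: of 12 neutrophil markers 2 fell (9 adjusted over the list alone; adjusted p = 1.2e-07, and adjusted p = 0.302 with an estimated correlation), and of 6 macrophage markers 3 fell, with Lyz2 at -2.14 ± 0.23 and Csf1r at -3.08 ± 0.59 (3 adjusted over the list alone; adjusted p = 2.0e-11, and adjusted p = 0.302 with an estimated correlation). With doublets kept, the neutrophil-marker list turned direction (adjusted p = 0.223) and S100a9 stood at 0.31. A fall of Il1b within B cells is not separated from these transcripts of other cells. edgeR called 379 of 10759 genes, 211 higher and 168 lower, against 225 with doublets kept, 49 without cluster 29, 25 and 158 without the first and second WT lung, and 206 without the second T238A lung.

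Dendritic cells of T238A lungs had higher levels of the adhesion receptor Adgrl3 (4.08 ± 0.39), the ribonuclease Ear2 (2.17 ± 0.31) and the lectin Clec4a2 (1.58 ± 0.28), and lower levels of the receptor Slamf9 (-2.23 ± 0.30), the lipopolysaccharide co-receptor Cd14 (-1.84 ± 0.28) and the interferon-induced tether Bst2 (-1.11 ± 0.19). The stress genes Atf3 (1.34 ± 0.21) and Fosb (1.00 ± 0.21), which also respond to tissue dissociation, were higher. Of 42 type I interferon genes 1 fell (4 adjusted over the list alone, with 1 higher; median -0.38, adjusted p = 1.6e-06, and adjusted p = 0.334 with an estimated correlation). The plasmacytoid cluster 19, led by Siglech, held 30.4% and 36.5% of the dendritic cells in WT lungs and 14% and 16.7% in T238A lungs, so a change within cells is not separated from their mix. edgeR called 55 of 8680 genes, 15 higher and 40 lower, and 230 and 164 without the first and second T238A lung, 84 and 164 without the first and second WT lung, 81 without the first T238A tumor and 85 without the first WT tumor.

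T cells of T238A lungs had lower levels of the checkpoint receptor Pdcd1 (-2.59 ± 0.33, edgeR adjusted p = 0.0065) and of the killer-cell receptor Klrd1 (-1.72 ± 0.20, 0.0015). Of 25 cytotoxic effector genes 1 fell and 14 adjusted over the list alone, with 1 higher (adjusted p = 2.5e-17, and adjusted p = 0.302 with an estimated correlation). Of 24 exhaustion and checkpoint genes 1 fell and 8 adjusted over the list alone (adjusted p = 3.0e-07, and adjusted p = 0.357 with an estimated correlation), and without the first WT lung the adjusted p of this list was 0.579. Cluster 5, led by Nkg7, Cd8b1 and Klrd1, held 31% and 30.1% of the T cells in WT lungs and 18.0% and 20.3% in T238A lungs. A change within cells is therefore not separated from the mix of clusters. The class also depends on the clustering. At Leiden resolution 0.5 the cluster named NK cell, led by Gzma, Ccl5 and Nkg7, held 1103 cells, against 439 at resolution 1.0. Cells counted as T cells here thus count as NK cells there. Transcripts of macrophages were lower in these T cells too, with 0 of 5 macrophage markers called and 4 adjusted over the list alone (adjusted p = 0.00172, and adjusted p = 0.46 with an estimated correlation), and without the first WT lung this list had an adjusted p of 0.975. Values for Ifng (-1.82 ± 0.36), Prf1 (-1.14 ± 0.25) and Foxp3 (1.32 ± 0.38) did not pass. edgeR called 9 genes, 1 higher and 8 lower, and 0 and 6 without the first and second T238A lung, 6 and 71 without the first and second WT lung, 17 and 17 without the first and second T238A tumor, and 15 and 15 without the WT tumors.

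Lung neutrophils differed in 1 gene by edgeR, the bile acid receptor gene Nr1h4 (-2.76 ± 0.41, adjusted p = 0.044), and DESeq2 called 2. An unadjusted edgeR p under 0.05 was found for 281 of 10907 genes, a smaller share than the 0.05 that chance alone gives. Il1b (-0.46 ± 0.21), Cxcl2 (-0.92 ± 0.24) and Arg2 (0.17 ± 0.17) did not pass. The count was 16 and 0 without the second and first WT lung, 4 and 0 without the first and second T238A lung, and 0 and 0 without the WT tumors.

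Whether T238A acted differently in the 2 tissues was tested with the interaction. In monocytes/macrophages 6 of 12 MHC class II genes rose in tumors and 5 of 12 fell in lungs, and the difference passed for H2-DMb1 (-3.01 ± 0.21, lung effect minus tumor effect in log2 ± SE; edgeR adjusted p = 0.00036), H2-Eb1 (-3.60 ± 0.34), H2-Ab1 (-3.17 ± 0.32), H2-Aa (-3.04 ± 0.35) and Cd74 (-2.66 ± 0.33). Interferon genes Irf7 (-1.58 ± 0.26), Oas2 (-1.56 ± 0.29) and Isg15 (-1.93 ± 0.27) differed too, as did Spp1 (-4.16 ± 0.38), C1qc (-3.28 ± 0.48) and Top2a (-2.20 ± 0.34). The lectin receptor Clec4e (1.18 ± 0.24), the chemokine Ccl9 (1.06 ± 0.20) and Abcd2 (1.38 ± 0.28) differed in the other direction. Of the 12 MHC class II genes 6 passed as lower (11 adjusted over the list alone; median -2.52, adjusted p = 1.6e-31, and adjusted p = 0.194 with an estimated correlation), and of 49 type I interferon genes 8 (31 adjusted over the list alone; median -0.79, adjusted p = 8.3e-24, and adjusted p = 0.31 with an estimated correlation). The lung part of this difference rests on a class with another mix of clusters, cluster 11 holding 55.3% and 73.9% in WT and 87.1% and 86.1% in T238A. No interaction was run within clusters. Over all genes 181 passed, 17 higher and 164 lower. This was 35 and 114 without the second and first T238A lung, 39 without the first WT lung and 75 without the second WT tumor. In neutrophils edgeR called 0 of 10907 genes (875 at an unadjusted p under 0.05, and 8 called by DESeq2). In T cells it called 0 of 9564, and DESeq2 called 1. There 384 genes had an unadjusted edgeR p under 0.05, a smaller share than the 0.05 that chance alone gives. On simulated counts the interaction test recovered 12% of 2-fold and 56% of 4-fold changes in neutrophils, and 8% and 58% in T cells. The counts of 0 therefore do not show that the T238A effect was equal in both tissues.

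Lungs and primary tumors were compared as a reference for the size of these effects. Per the labels, cell viability was lower in the tumor samples than in the lung samples, with ranges that do not overlap. An effect of viability is therefore not separated from that of tissue. Neutrophils of lungs carried more granule genes of young neutrophils and far less inflammatory and hypoxia RNA. They also lay in other clusters: cluster 1, led by G0s2 and Cxcl2, held 88.7% to 95.5% of the neutrophils in tumors and 0.189% to 1.15% in lungs. Ly6g, a surface marker of neutrophils, was 2.78 ± 0.15 higher in lungs (log2 ± SE) and the chitinase-like Chil3 2.90 ± 0.47. The chemokines Cxcl3 (-8.44 ± 0.27) and Ccl3 (-6.86 ± 0.24), the coagulation factor gene F10 (-6.22 ± 0.18) and the transglutaminase Tgm2 (-6.15 ± 0.17) were lower. Of 29 NF-kB targets 28 were lower, of 30 hypoxia genes 28 were lower, and of 27 granule genes 22 were higher (28, 28 and 24 adjusted over the list alone; adjusted p = 3.9e-38, 4.4e-38 and 5.3e-10, and adjusted p = 0.0602, 0.0728 and 0.232 with an estimated correlation). edgeR called 6411 genes, 3458 higher and 2953 lower in lungs.

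Most of this class were monocytes in lungs and macrophages in tumors, with cluster 11 at 55.3% to 87.1% in lungs and 0.248% to 1.60% in tumors. Lung monocytes/macrophages had higher Hp, the hemoglobin scavenger haptoglobin (4.25 ± 0.17), and lower levels of the lipid droplet gene Hilpda (-6.12 ± 0.31), the platelet factor gene Pf4 (-5.25 ± 0.35) and Ptgs2, an enzyme of prostaglandin synthesis (-5.04 ± 0.61). Of 45 cell cycle genes 41 were lower and 2 higher (41 and 2 adjusted over the list alone; adjusted p = 4.5e-14, and adjusted p = 0.232 with an estimated correlation). The neutrophil gene S100a9 was 4.58 ± 0.62 higher in them, and neutrophils were more frequent in lungs. In T cells of lungs 14 of 16 naive and memory genes were higher (15 adjusted over the list alone; adjusted p = 8.8e-37, and adjusted p = 0.0602 with an estimated correlation), such as Ccr7 (3.02 ± 0.33), the chemokine receptor that guides cells to lymph nodes. Cluster 25, led by Lef1 and Dapl1, held 41.4% to 55.1% of T cells in lungs and 0.952% to 4.43% in tumors. Of 24 exhaustion genes 19 were lower and 1 higher, with Rgs16 (-4.05 ± 0.30) among the lower, and 22 and 1 adjusted over the list alone (adjusted p = 4.4e-23, and adjusted p = 0.0602 with an estimated correlation). The opioid precursor Penk (-4.28 ± 0.26) was also lower. edgeR called 6193 genes in monocytes/macrophages and 2284 in T cells.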

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

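The tests of macrophage cluster mix, lung monocyte clusters and free RNA were chosen only after the result was seen, while the bounds for gene length were written before it.

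The T238A effect differed between lungs and primary tumors for 181 genes in monocytes/macrophages, and for 14 gene lists in these cells, 11 in T cells and 7 in neutrophils. Leaving out the second T238A lung gave 35 genes, the first WT lung 39, the second WT tumor 75, and the first T238A lung 114. In lungs the T238A effect went with another mix of monocyte/macrophage clusters. Fitted on the lung libraries alone, T238A against WT gave 277 genes with all clusters and 1 with clusters 11 and 31 only. H2-Eb1 then stood at -0.79, and Top2a (0.51) and Mif (0.022) turned sign, none called. The lung calls thus rest largely on cells of the other clusters. Much of the lung part of the difference between tissues therefore goes with this mix. The interaction itself was not run within clusters. The list calls were lost with an estimated correlation (lowest adjusted p = 0.194).

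Of the rise of interferon-stimulated and MHC class II genes in tumor macrophages, a median of 0.64 and 1.47 was left against genes matched on span and expression, which argues against gene length as the whole cause. A different mix of macrophage clusters left an interferon median of at least 0.55 within each of clusters 0, 2 and 3, against 0.62 in the class, but the MHC class II median was 0.64 in cluster 2, 1.22 in cluster 0 and 1.24 in cluster 3, against 1.32 in the class. Part of the MHC class II rise may therefore come from the mix of clusters. Free RNA cannot be told apart for the interferon list, whose median was -0.14 in neutrophils but 0.35 in T cells and 0.46 in cancer cells of the same tumors. An effect of the ENPP1 construct stays open and untested, as do differences between mice and between the cell lines.

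Lower oxidative phosphorylation genes in T238A tumors were weighed against gene length, since short genes were lower and long genes higher. After matching on span and expression the list's median moved from -0.37 to -0.0432 in neutrophils, from -0.39 to -0.156 in monocytes/macrophages and from -0.39 to -0.148 in cancer cells. In these cells a larger part of intron-containing RNA in the T238A libraries could account for most of the fall. In T cells -0.321 of -0.53 was left, with quartiles of -0.45 and -0.11, so length alone does not account for it there. An effect of the construct was not tested apart from the libraries.

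By edgeR on numbers of cells, the T238A effect on the share of cancer epithelial cells was lower in lungs than in tumors (log2 ratio -4.75, adjusted p = 0.000736), and so was that on fibroblasts (-3.54, adjusted p = 0.0162). The clusters led by thymic genes held 9.39% (cluster 33) and 1.63% (cluster 36) of cells in the first WT lung, outside every tested class, against at most 0.348% and 0.151% in the other lungs.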

How the results depend on the processing

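The top 5% of doublet scores, the handling of clusters led by thymic genes, lung monocyte clusters only and the Vpreb3-led cluster were chosen as alternatives only after the result was seen. Counts of genes are edgeR calls unless named otherwise, against 79, 333, 5 and 267 in neutrophils, monocytes/macrophages, T cells and cancer cells of tumors, 1, 258, 9, 379 and 55 in neutrophils, monocytes/macrophages, T cells, B cells and dendritic cells of lungs, and 0, 181 and 0 in neutrophils, monocytes/macrophages and T cells for the interaction. Where a count moved, the cause was not tested. Without the filter on low counts they were 403, 1165, 188 and 1719 in tumors, 25, 803, 130, 583 and 189 in lungs, and 19, 703 and 63 for the interaction. DESeq2 gave 376 in tumor neutrophils, 76 in T cells and 595 in cancer cells, 2, 415, 21, 115 and 17 in lungs, and 8, 344 and 1 for the interaction. Its size factors in edgeR gave 134 in tumor neutrophils. Each tissue alone gave 48, 96 and 3 in neutrophils, monocytes/macrophages and T cells of tumors and 0 in lung neutrophils. The replicate number as a block gave 8 and 1106 in T cells and cancer cells of tumors, 3, 26 and 354 in neutrophils, T cells and dendritic cells of lungs, and 303 and 3 in monocytes/macrophages and T cells for the interaction; the labels do not tie these numbers to a mouse, and correlations of deviations between libraries of the same number were -0.044 to 0.243. Stricter cell filters gave 0 in lung neutrophils. Leiden resolution 0.5 gave 0, 116 and 0 in neutrophils, monocytes/macrophages and T cells of lungs and 104 in monocytes/macrophages for the interaction. It gave no value for T cells in the other contrasts or for dendritic cells, with too few cells in a library. The T-cell clusters then held 4 and 25 cells in the second WT tumor, and the second T238A lung held 23 dendritic cells. The cluster named NK cell held 86 and 37 cells in WT tumors and 173 and 57 in T238A tumors, against 5, 6, 25 and 3 at resolution 1.0. The T-cell class and its share in tumors thus depend on the resolution. Without the top 5% of doublet scores T cells had 10 in tumors and 18 in lungs, and with thymocyte-led clusters counted as T cells 4 in lungs. Lung monocyte clusters 11 and 31 alone, fitted on the lung libraries alone, gave 1, with Mif at 0.022 and Top2a at 0.51. All clusters in such a fit gave 277. Lung B cells had 225 with doublets kept, where S100a9 stood at 0.31 and the granule and neutrophil-marker lists turned direction (adjusted p = 0.210 and 0.223). Without cluster 29 they had 49. Signs then turned for Akap12 (-0.10), Sox4 (-0.23) and Reln (-2.36), none called (edgeR adjusted p = 0.982, 0.944 and 0.827). Gene lists called fell from 31 and 73 to 0 and 0 by camera with an estimated correlation.

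By edgeR on numbers of cells the log2 ratio was 2.62 for B cells and, set by 0 and 0 cells in WT against 20 and 1 in T238A, 6.99 for innate lymphoid type 2 cells in tumors and -4.57 for cancer cells in lungs. The T-cell share in lungs turned to -0.616 points among immune cells and -0.467 points without thymocyte-led clusters. When each library was left out in turn, the lone library left in its group was assumed to vary like the other groups. Counts then ranged over 1 to 103, 27 to 398, 0 to 39 and 0 to 324 in tumors, 0 to 16, 61 to 285, 0 to 71, 25 to 343 and 81 to 230 in lungs, and 0 to 4, 35 to 220 and 0 to 17 for the interaction. Shares ranged over -14.2 to 2.84 points (neutrophils) and -5.30 to 9.99 (cancer cells) in tumors, and -15.7 to 15.2 (neutrophils), -3.89 to 2.83 (monocytes/macrophages), -3.42 to 4.07 (T cells) and -1.42 to 0.202 (NK cells) in lungs. Lists called in lungs ranged over 42 to 90. The adjusted p ranged over 4.28e-07 to 0.734 and 1.60e-21 to 0.253 for the oxidative phosphorylation and cell cycle lists in lung neutrophils, and over 7.55e-12 to 0.786, 2.80e-11 to 0.975 and 2.43e-08 to 0.983 for the MHC class II, complement and lysosome, and regulatory T lists in lung T cells.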

Other observations

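The test of the dissected tissue and the counts of other splits of the libraries were chosen only after the result was seen; those of doublets and shared barcodes were not.

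Rarer cells of lungs were compared as well. Basophils or mast cells made up 1.19% ± 0.534 of T238A lungs and 0.557% ± 0.0779 of WT lungs (SD, n = 2), and innate lymphoid type 2 cells 0.489% ± 0.178 and 0.224% ± 0.0529. Endothelial cells stood at 0.0859% ± 0.0068 and 0.261% ± 0.0294. For these 3 classes the groups did not overlap, with an exact permutation p of 0.333. By edgeR on numbers of cells none of the 3 passed (adjusted p = 0.223, 0.234 and 0.135). Cells led by the granulocyte-monocyte progenitor genes Mpo, Ctsg and Elane made up 1.24% and 1.11% of T238A lungs and 0.492% and 0.826% of WT lungs. In lung B cells, dissociation and heat-shock genes were lower, with 7 of 28 called and 1 higher (adjusted p = 1.3e-07, and adjusted p = 0.357 with an estimated correlation).

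The B-cell cluster led by Vpreb3, a gene of developing B cells, made up 3.07% and 5.38% of cells in T238A lungs and 0.141% and 0.346% in WT lungs. Lymphoid tissue dissected with the lungs cannot be told apart: the cluster made up 0.373% of pooled T238A tumor cells (20 of 5364) and 0.0204% of WT tumor cells (1 of 4905), but WT tumors held 5 and 5 B cells, too few to compare. Doublets are unlikely to be the source, with 1.45% of its cells (8 of 550) among the top 5% of doublet scores. Carry-over of barcodes from lung libraries is unlikely too, with 0 of its 20 tumor barcodes shared (0%, up to 16.8%). A response of B cells to the construct stays open as a hypothesis, as do differences between mice and between the cell lines.

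For lungs against primary tumors, the 8 libraries can be split 4 against 4 in 35 ways. The fit held the split and the construct as terms, or the split alone where both coincide. By edgeR, 1 of the 35 splits, the real one, gave as many genes in neutrophils (6357, highest other 0). The same held in monocytes/macrophages (5839, highest other 0) and in T cells (2388, highest other 0). Each of the other splits mixes both tissues, so the tissue difference counts as spread within their groups. The test therefore cannot exclude chance and says no more than that the libraries part by tissue.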
